A study of Homo sapiens with 5 samples.

How the data were processed

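Small RNA was sequenced from HEK293T, an established human embryonic kidney cell line, carrying short hairpin RNA constructs in a lentiviral vector. The constructs were NTC, read here as a non-targeting control, 2 hairpins against MEF2C and 2 hairpins against ZNF460. Each of the 5 constructs is 1 sample in the labels and 3 columns of values. The columns were taken as the 3 biological replicates that the series describes, which the labels do not state column by column; if they were repeat libraries of 1 culture, SD, SE and p-values would cover the spread between libraries alone. Per the labels' protocols, libraries were made from total RNA with a kit for small RNA and sequenced as paired reads, and the authors shortened the reads from the end with cutadapt. Per the labels' protocols, libraries were purified by gel or by magnetic beads, the latter with more reads per sample; which library had which purification is not marked. The aligner, the genome build and the handling of reads that match several tRNA genes are not given in the sources used here.

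The deposited values are transcripts per 1000000 (TPM) computed by the authors for 355 nuclear tRNA genes, which make up 228 isodecoders (genes of 1 mature sequence name). The listed genes sum to between 96.3% and 98.5% of 1000000 TPM per library, so the scaling also used features outside the table. TPM values were checked for steps of 1 read divided by the mature tRNA length, taken from RefSeq for 316 genes and from the steps themselves for 39. Every value came within 0.05 of a whole number of reads in every library. The recovered reads per library ranged from 498793 to 1562836, so 3 reads of a tRNA of 75 nt correspond to between 1.85 and 5.82 TPM. Reads carry no molecular identifiers, so such limits cover counting error only.

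Gene copies of 1 isodecoder were tested for an even split of reads in 701 pairs of isodecoder and library. A chi-square p under 0.05 was found in 23.5% of these pairs, and the copies of 13 of 50 isodecoders differed in more than 20% of their libraries. Copies of the other isodecoders did not differ so often. Each gene was still tested and counted on its own, also within the lists. Counts of genes below are therefore counts of copies, and genes of 1 isodecoder are not independent measurements. Chromosome positions are not given. The 292 genes with a mean of at least 10 TPM, from 189 isodecoders, were tested.

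Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with a mean-variance trend and a mean per construct. A knockdown was the mean of its 2 hairpins. All p-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) are those of the limma fit. TPM was also summed per isotype (amino acid, with initiator methionine and selenocysteine separate) and per isoacceptor (amino acid and anticodon) and tested in the same way. Gene lists by isotype, by the first base of the anticodon, by long variable arm, by intron-containing families, by isoacceptors known for abundant 5′ fragments and by amino acid class were tested with camera from limma at a preset correlation of 0.01 and with an estimated correlation. Lists needed at least 3 members, which left 33. Correlations and covariances between hairpins and between targets were set beside simulations of unchanged libraries that share the NTC libraries, with 200 draws. The correlation between hairpins was also computed with the variance of replicates and the shared NTC taken out, with a 95% interval from 1000 bootstrap draws of isodecoders. This was tested on simulated data with either a shared response or unrelated changes, and not with both together.

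Genes are named by a rule. For each target, among genes with a mean of at least 100 TPM and both hairpins on the same side of NTC, the 12 highest and the 12 lowest by the hairpin with the smaller change were taken, those past the test first. Between targets the 5 highest and 5 lowest were taken among genes whose libraries did not overlap. The 5 genes of highest mean TPM and each initiator methionine or selenocysteine gene with at least 100 TPM were added. Any other gene named was chosen after its values were seen.

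The tests, the lists, the naming rule and most alternatives were chosen before the data were examined. These alternatives were other pseudocounts and filters, centring of each library on its median gene, no trend, summed isodecoders, single hairpins, the libraries of 1 target alone, hairpin number as a block, limma with voom on the recovered reads, and each library left out in turn. The hairpin as the unit of replication, the replicate number as a block, scaling to the tRNAs other than glycine, thinning to the smallest library and the correlation with replicate variance taken out were chosen after seeing the data.

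The tests were run on simulated data with 60 changed genes in each of 20 draws. Limma recovered 42.3% of changes of 1.5-fold, 74.8% of changes of 2-fold and 96.8% of changes of 4-fold. TPM shares a fixed total, and 15.4% of the simulated calls were false; 60.9% of the false calls were glycine genes. With the simulated shift of the unchanged genes taken out, which reached 0.11 on the log2 scale, 4.62% were false. Small changes of abundant tRNAs can therefore come from the shared total alone. No glycine gene was changed in these simulations. In the real libraries the median gene changed further, by -0.46 with MEF2C and -0.23 with ZNF460 knockdown on the log2 scale. The simulated percentages of false calls therefore do not carry over to the real calls. After centring, 92 of 164 MEF2C calls and 14 of 55 ZNF460 calls were kept in the same direction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for reading, simulation and plots.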

Results

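Reads on tRNA genes were measured by small RNA sequencing in 15 libraries of HEK293T cells. There were 3 each for the NTC control, for each of 2 hairpins against MEF2C and for each of 2 hairpins against ZNF460. The values do not show whether reads came from whole tRNAs or from fragments of them. A rise or fall of a tRNA below therefore means a change in its reads. MEF2C is a transcription factor of the MADS-box family and ZNF460 is a zinc finger protein; the series describes both as candidate regulators of tRNA. The recovered reads on tRNA genes were 1562836, 1506404 and 618426 in NTC replicates 1 to 3. MEF2C hairpin 1 had 498793, 505350 and 531024 reads and hairpin 2 had 862700, 626408 and 1028456. ZNF460 hairpin 1 had 1490230, 1443379 and 1152785 reads and hairpin 2 had 1010621, 1237143 and 1517887. The table lists tRNA genes alone, so the mRNA levels of MEF2C and ZNF460 were not analysed here.

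Glycine and glutamate tRNAs made up most of the signal. In NTC libraries the 28 glycine genes summed to 705966 ± 7131 TPM (SD, n = 3) and the 15 glutamate genes to 172789 ± 3589 TPM. Lysine followed at 32247 TPM, so a scale that leaves out glycine is set mostly by glutamate. The 5 genes of highest mean, tRNA-Gly-GCC-1-1 to tRNA-Gly-GCC-1-5, lay between 90338 and 90791 TPM each in NTC and passed the test in neither knockdown against NTC. Their adjusted p in limma ranged from 0.202 to 0.828 for MEF2C and from 0.566 to 0.762 for ZNF460. These results are for values as deposited and depend on the scaling. The Gly-GCC pool, which holds these genes, was higher with MEF2C knockdown by 0.16 on the log2 scale as deposited. It was higher by 0.73 after centring (adjusted p = 0.00098 in limma) and by 0.69 after scaling to the tRNAs other than glycine. Between the targets tRNA-Gly-GCC-1-1 and tRNA-Gly-GCC-1-2 passed, calls lost under 12 and 6 alternatives.

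The first comparison asked which tRNA genes differ from NTC when MEF2C is targeted. The asparagine gene tRNA-Asn-GTT-3-1 fell most among the named genes, from 470.3 ± 31 TPM (SD, n = 3) in NTC to 23.6 ± 13.2 with hairpin 1 and 32.4 ± 6.24 with hairpin 2, 17.6-fold lower (log2 -4.13, SE 0.268, adjusted p = 2.1e-10 in limma). The valine gene tRNA-Val-CAC-2-1 fell from 7285 ± 213 TPM to 1723 ± 19.97 and 1444 ± 147 TPM, 4.62-fold lower (log2 -2.21, SE 0.0784). The lysine genes tRNA-Lys-CTT-8-1 and tRNA-Lys-CTT-5-1 fell 8.67-fold and 7.60-fold, and tRNA-Lys-CTT-11-1 fell 4.50-fold. The arginine genes tRNA-Arg-ACG-2-1 to tRNA-Arg-ACG-2-4 fell between 5.22-fold and 6.36-fold, tRNA-Arg-CCT-3-1 4.70-fold and tRNA-Arg-CCG-2-1 4.68-fold, and the tryptophan gene tRNA-Trp-CCA-4-1 fell 4.21-fold. All 12 of these genes lay below every NTC library in 6 of 6 MEF2C libraries and passed the test under each of the 30 alternatives run for them.

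The threonine gene tRNA-Thr-TGT-1-1 rose most among the named genes, from 53.7 ± 9.64 TPM in NTC to 223 ± 46.4 with hairpin 1 and 134 ± 41.8 with hairpin 2, 3.14-fold (log2 1.65, SE 0.199, adjusted p = 4.87e-07 in limma, higher in 6 of 6 libraries). The serine gene tRNA-Ser-TGA-4-1 rose 2.24-fold, tRNA-Lys-TTT-1-1 1.83-fold, tRNA-Lys-TTT-2-1 1.71-fold, tRNA-Asp-GTC-1-1 1.66-fold and tRNA-Thr-CGT-4-1 1.56-fold. Of these, tRNA-Lys-TTT-2-1 and tRNA-Asp-GTC-1-1 were higher in 5 of 6 libraries and did not pass with hairpin 2 alone. Without NTC replicate 3, tRNA-Thr-CGT-4-1 no longer passed the test. With the hairpins as the units of replication none of the 12 higher genes named in this paragraph passed in limma (adjusted p = 0.0925 for tRNA-Thr-TGT-1-1). The glycine genes tRNA-Gly-GCC-2-2, tRNA-Gly-GCC-2-3, tRNA-Gly-GCC-2-4, tRNA-Gly-GCC-2-6, tRNA-Gly-GCC-3-1 and tRNA-Gly-GCC-5-1 rose by between 1.34-fold and 1.36-fold, for example tRNA-Gly-GCC-2-2 from 24314 ± 620 to 31414 ± 1342 and 35090 ± 2011 TPM. These glycine genes had nearly equal values and are not separate evidence. In NTC libraries tRNA-Gly-GCC-2-2 had 23893 to 25026 TPM, tRNA-Gly-GCC-3-1 23899 to 25041 and tRNA-Gly-GCC-5-1 23828 to 25140.

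Summed by isotype, 16 of 21 pools differed between MEF2C knockdown and NTC, 3 higher and 13 lower. After centring 13 passed, 8 higher and 5 lower, and after scaling to the tRNAs other than glycine 13, 7 higher and 6 lower. The balance of higher and lower pools thus depended on the scaling. Asparagine tRNA was 6.91-fold lower (log2 -2.79, SE 0.211), arginine 3.34-fold, glutamine 3.07-fold, tryptophan 2.96-fold and valine 1.98-fold lower, each below every NTC library in 6 of 6 libraries. Most of the asparagine and tryptophan sums is 1 gene each. In NTC libraries tRNA-Asn-GTT-3-1 had 439 to 501 TPM and its pool 534 to 600. There tRNA-Trp-CCA-4-1 had 663 to 875 TPM and its pool 785 to 1028. Initiator methionine tRNA, which starts translation, rose 1.67-fold (log2 0.74, SE 0.244, higher in 5 of 6 libraries) and aspartate tRNA 1.65-fold (log2 0.72, SE 0.222, higher in 5 of 6). Initiator methionine lost its call without NTC replicate 3, and aspartate, isoleucine and methionine lost theirs as means of log2 values. Glycine tRNA rose 1.12-fold as a sum, to 764032 ± 14724 and 824524 ± 11566 TPM, while the mean of its genes' log2 values fell by 0.21. Within glycine, the sum of genes with the TCC anticodon fell 1.86-fold (log2 -0.90, SE 0.116). Lysine, phenylalanine, leucine and selenocysteine tRNAs were lower (log2 -0.74, -0.88, -0.75 and -0.72), calls that were lost when each library was centred on its median gene. Glutamate, isoleucine, methionine and serine were lower as deposited (log2 -0.43, -0.50, -0.36 and -0.43). After centring glutamate, isoleucine and serine did not pass (log2 0.14, 0.07 and 0.14, adjusted p = 0.437, 0.588 and 0.275 in limma), and methionine passed as higher (log2 0.21, adjusted p = 0.0184). After scaling to the tRNAs other than glycine, glutamate passed as higher (log2 0.10, adjusted p = 0.0459 in limma). Isoleucine also lost its call without NTC replicate 1, and methionine without NTC replicate 1 or NTC replicate 2.

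**Figure D1:**
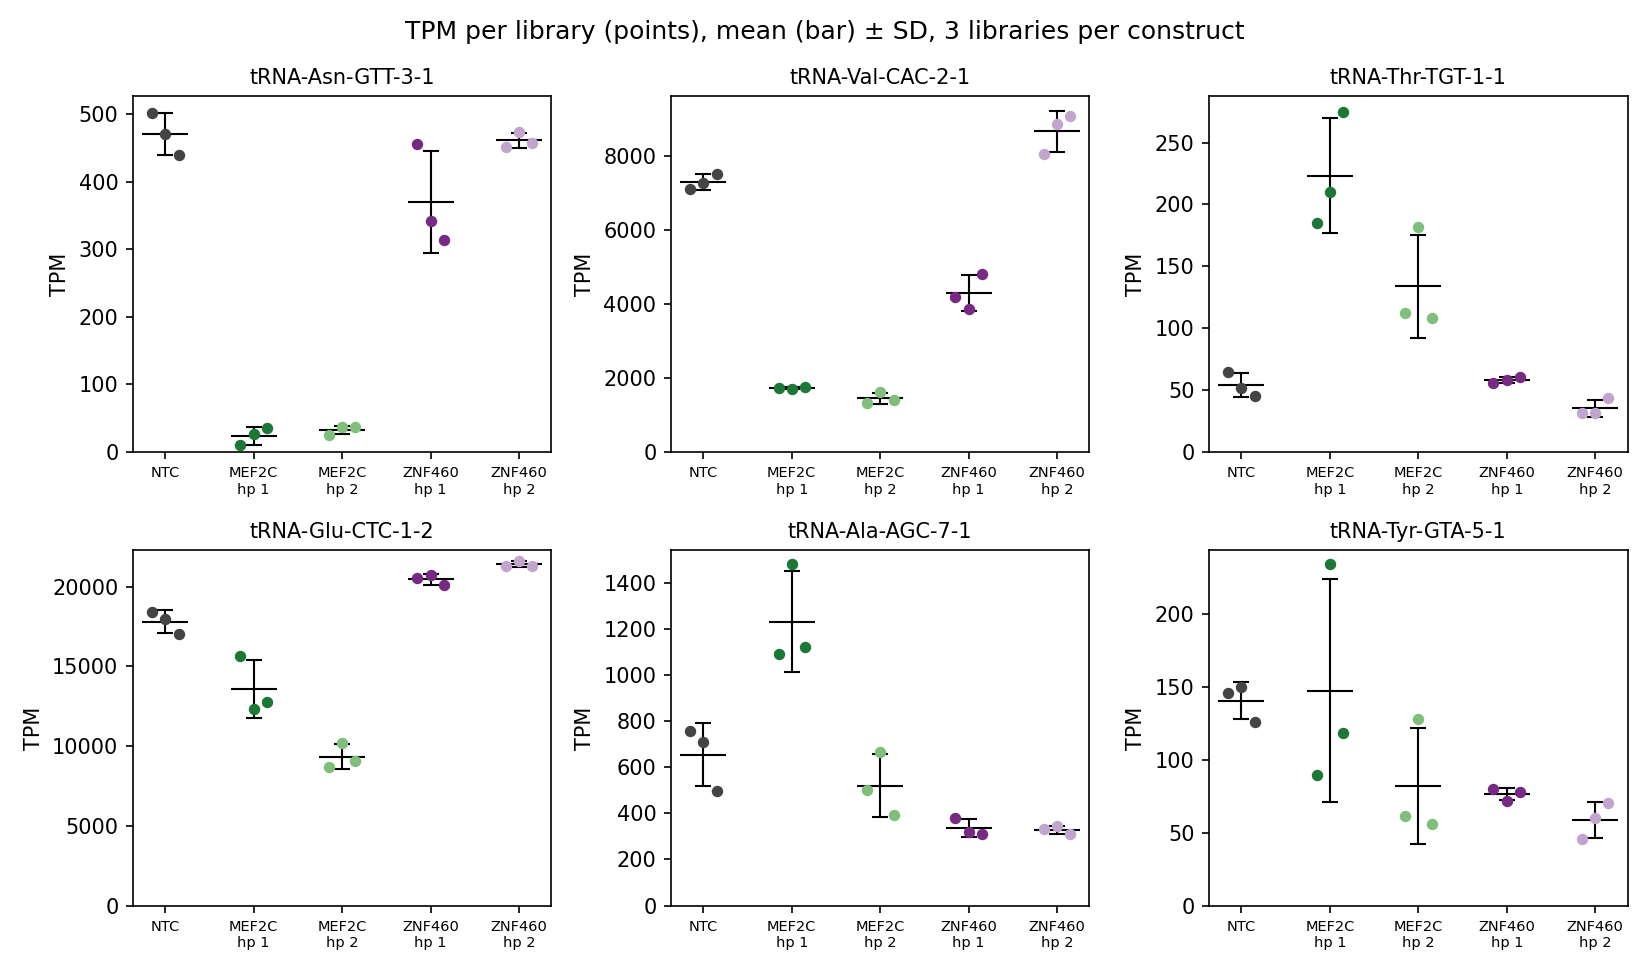
TPM of 6 tRNA genes in each library (points), with the mean and SD of the 3 libraries per construct; hp stands for hairpin and each axis starts at 0. With either MEF2C hairpin tRNA-Asn-GTT-3-1 and tRNA-Val-CAC-2-1 lie below every NTC library, and with either ZNF460 hairpin tRNA-Ala-AGC-7-1 and tRNA-Tyr-GTA-5-1 do.

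**Figure D2:**
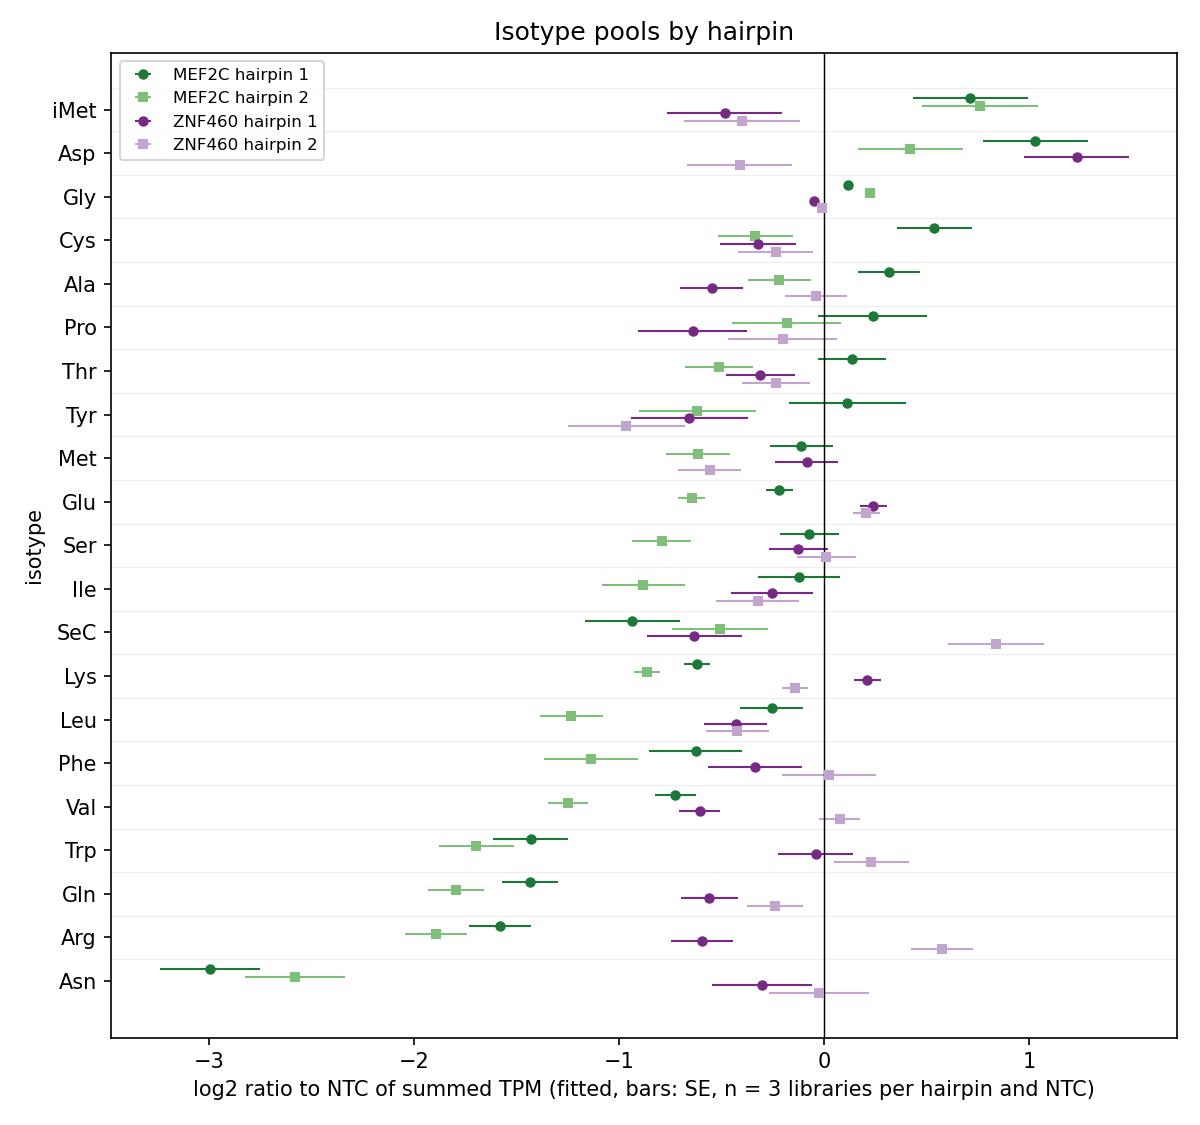
Fitted log2 ratio to NTC of the summed TPM of 21 isotypes for each hairpin, with SE bars and 3 libraries per construct. Asparagine, arginine, glutamine and tryptophan lie below 0 with both MEF2C hairpins. Arginine and selenocysteine lie on opposite sides of 0 with the 2 ZNF460 hairpins. The ZNF460 averages of glutamine, selenocysteine and valine change sign with the scaling.

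Over all genes, 164 of 292 differed between MEF2C and NTC libraries in limma, 27 higher and 137 lower. The genes called came from 19 isodecoders with a higher gene and 89 with a lower one. At least 2-fold changes were found in 70 lower and 7 higher genes, and 21 genes were at least 4-fold lower. The median gene changed by -0.46 on the log2 scale. Relative to it, tRNA-Asn-GTT-3-1 changed by -3.68, tRNA-Val-CAC-2-1 by -1.75, tRNA-Gly-GCC-2-2 by 0.91 and tRNA-Thr-TGT-1-1 by 2.11. With libraries centred on the median gene 169 genes passed, 104 higher and 65 lower, and with values scaled to the tRNAs other than glycine 166 passed, 96 higher and 70 lower, so the predominance of lower genes depended on the scaling. With the 2 hairpins as the units of replication 43 genes passed, 1 higher and 42 lower.

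Among the lists, 19 of 19 glutamine genes fell with MEF2C knockdown, 19 also adjusted over the list alone, and 19 passed as lower under both other scalings. Of 27 arginine genes 26 fell, 26 adjusted over the list alone, against 16 under either other scaling. Of the 22 amide amino acid genes (asparagine and glutamine) 21 fell, 22 adjusted over the list alone, and 20 after centring. Of the 46 basic amino acid genes (arginine and lysine) 39 fell and 3 rose, the same numbers as adjusted over the list alone, against 21 lower and 4 higher after centring. The preset-correlation test called these 4 lists and anticodons that start with C lower than other tRNAs, but none of the 5 passed with an estimated correlation (adjusted p = 0.549 with an estimated correlation for the 4 and adjusted p = 0.904 with an estimated correlation for the last). Of the genes whose anticodon starts with C, 53 of 97 fell and 7 rose as deposited but 29 were lower and 30 higher after centring. It called cysteine, glycine, initiator methionine, anticodons that start with G, small amino acids and sulphur amino acids higher than other tRNAs. None of these passed with an estimated correlation either: adjusted p = 0.904 with an estimated correlation for cysteine and sulphur and adjusted p = 0.549 with an estimated correlation for the other 4. Their members that rose and fell numbered 2 and 1 of 21, 10 and 11 of 28, 3 and 0 of 4, 11 and 13 of 67, 14 and 26 of 73, and 5 and 3 of 35. After centring the same counts were 19 and 1, 16 and 3, 4 and 0, 38 and 4, 36 and 4, and 31 and 3, so the balance within glycine, anticodons that start with G and the small class turned with the scaling. Long variable arm, intron-containing families, abundant 5′ fragments and the acidic, branched-chain and aromatic classes passed neither test, nor did the other isotypes and anticodon groups.

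The second comparison asked the same of ZNF460. The alanine genes tRNA-Ala-AGC-3-1, tRNA-Ala-AGC-7-1 and tRNA-Ala-TGC-1-1 fell 1.97-fold, 1.94-fold and 1.93-fold, each below every NTC library in 6 of 6 libraries. For tRNA-Ala-AGC-7-1 the values were 654.7 ± 137 TPM in NTC, 336.8 ± 38.2 with hairpin 1 and 328.4 ± 18.1 with hairpin 2 (SD, n = 3; log2 -0.96, SE 0.167, adjusted p = 0.00477 in limma). The tyrosine genes tRNA-Tyr-GTA-5-1, tRNA-Tyr-GTA-8-1, tRNA-Tyr-GTA-5-2, tRNA-Tyr-GTA-5-3 and tRNA-Tyr-GTA-1-1 fell by between 1.69-fold and 2.09-fold, with tRNA-Tyr-GTA-5-1 at 140.3 ± 12.7 TPM in NTC and 76.3 ± 4.30 and 58.6 ± 12.6 TPM with the hairpins. The leucine genes tRNA-Leu-TAG-2-1, tRNA-Leu-TAG-1-1 and tRNA-Leu-TAG-3-1 fell 1.66-fold, 1.53-fold and 1.48-fold and the methionine gene tRNA-Met-CAT-5-2 fell 1.46-fold. The calls of these 4 genes and of tRNA-Tyr-GTA-1-1, tRNA-Tyr-GTA-5-2 and tRNA-Tyr-GTA-5-3 were lost after centring. With hairpin 1 alone these 3 tyrosine genes and tRNA-Met-CAT-5-2 did not pass, and with hairpin 2 alone tRNA-Tyr-GTA-1-1 and tRNA-Leu-TAG-1-1 did not.

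Higher with ZNF460 knockdown were tRNA-Arg-TCT-1-1, 1.56-fold (log2 0.65, SE 0.21, adjusted p = 0.0381 in limma, higher in 6 of 6 libraries), and the glutamate genes tRNA-Glu-CTC-1-1 to tRNA-Glu-CTC-1-7 and tRNA-Glu-CTC-2-1, by between 1.17-fold and 1.18-fold. For tRNA-Glu-CTC-1-2 the values were 17795 ± 714 TPM in NTC and 20456 ± 349 and 21410 ± 187 TPM with the hairpins (log2 0.23, SE 0.0615), above every NTC library in 6 of 6. None of these 9 genes passed in limma without a trend. The call of tRNA-Arg-TCT-1-1 was also lost with hairpin 2 alone (adjusted p = 0.244) and without any 1 of the NTC or ZNF460 libraries. The genes tRNA-Glu-CTC-1-1, tRNA-Glu-CTC-1-3, tRNA-Glu-CTC-1-5 and tRNA-Glu-CTC-1-7 did not pass with hairpin 2 alone, nor tRNA-Glu-CTC-1-4 with hairpin 1 alone. The 8 glutamate genes are copies of 2 isodecoders, and none of them passed after scaling to the tRNAs other than glycine. The 2 isodecoders are not separate evidence either. In NTC libraries tRNA-Glu-CTC-2-1 had 16720 to 18136 TPM and tRNA-Glu-CTC-1-4 had 16756 to 18184. In ZNF460 libraries they had 19662 to 21030 and 19592 to 21334 TPM. Glutamate is the largest part of that scale, which by construction removes much of a glutamate rise, so this loss does not speak against the rise. The genes tRNA-Lys-TTT-4-1, tRNA-Thr-CGT-4-1 and tRNA-Glu-TTC-2-2 were taken by the naming rule with log2 values of 0.33, 0.19 and 0.15 and did not pass (adjusted p = 0.128, 0.505 and 0.257).

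Of 21 isotype pools 5 passed against NTC, 1 higher and 4 lower. After centring 6 passed, 6 higher and 0 lower, and after scaling to the tRNAs other than glycine 11, 1 higher and 10 lower. Glutamate rose 1.17-fold (log2 0.22, SE 0.0568, higher in 6 of 6 libraries), a call lost as a mean of log2 values, and tyrosine fell 1.76-fold (log2 -0.81, SE 0.247) and leucine 1.35-fold (log2 -0.43, SE 0.133), each below every NTC library in 6 of 6. The tyrosine and leucine calls were lost after centring. Glutamine and valine were lower as deposited (log2 -0.40 and -0.27) but at 0.02 and 0.16 after centring, where they did not pass. As deposited, glutamine was also below every NTC library in 6 of 6. Valine was above the NTC mean in 3 of 6 libraries and lost its call as a mean of log2 values. The number of pools in limma was 0 without NTC replicate 1, without NTC replicate 2 or without ZNF460 hairpin 1 replicate 2, where 5, 5 and 6 had an unadjusted p under 0.05, and 1 without ZNF460 hairpin 2 replicate 1. It was 8 without NTC replicate 3 or without MEF2C hairpin 1 replicate 1, and 11 with values scaled to the tRNAs other than glycine.

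Over all genes, 55 of 292 differed between ZNF460 and NTC libraries, 9 higher and 46 lower, and the median gene changed by -0.23 on the log2 scale. Relative to it, tRNA-Ala-AGC-7-1 changed by -0.72, tRNA-Tyr-GTA-5-1 by -0.83 and tRNA-Glu-CTC-1-2 by 0.47. After centring 62 genes passed, 57 higher and 5 lower, and after scaling to the tRNAs other than glycine 75 passed, 1 higher and 74 lower. Glutamate, which rose as deposited, is the largest part of the latter scale, so its rise by construction lowers the other values there. The count rested on single libraries: it was 0 without NTC replicate 1, where 73 genes had an unadjusted p under 0.05 in limma, 6 without NTC replicate 2 and 25 without NTC replicate 3. It was 7 and 26 without replicates 2 and 3 of ZNF460 hairpin 1, and 8, 12 and 9 without replicates 1, 2 and 3 of ZNF460 hairpin 2. No gene passed in every one of these fits, and with the hairpins as the units of replication limma called 0 genes, 1 with an unadjusted p under 0.05. Limma with voom on the recovered reads called 79, limma on the NTC and ZNF460 libraries alone 123, and limma without a trend 26. For MEF2C, limma on the NTC and MEF2C libraries alone called 153. The main fit takes 1 spread from the libraries of both targets, so its 164 and 55 calls do not rank the targets.

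The lists called for ZNF460 were led by abundant 5′ fragments, of which 8 of 52 genes rose and 1 fell, the same as adjusted over the list alone. Glutamate (8 of 14 rose) and acidic amino acids (8 of 15 rose, 8 adjusted over the list alone) were called higher than other tRNAs as well. These 3 lists also passed with an estimated correlation: adjusted p = 0.00143 with an estimated correlation for abundant 5′ fragments and adjusted p = 0.0393 with an estimated correlation for the other two. All of their genes that rose were the 8 Glu-CTC genes. The list test uses every member, and whether the 3 calls rest on these 8 genes was not tested. None of the 8 rose after scaling to the tRNAs other than glycine, a scale set mostly by glutamate, so this loss does not speak against a rise. With the preset correlation alone, 11 more lists were called, of which none passed with an estimated correlation (adjusted p = 0.604 with an estimated correlation for lysine, the lowest, to adjusted p = 0.843 with an estimated correlation for amide and sulphur, the highest). Tyrosine genes were lower, 7 of 12 and 10 adjusted over the list alone, as were leucine (10 of 30), glutamine (6 of 19, 12 adjusted over the list alone), methionine (7 of 10) and valine (4 of 9). Also called lower were anticodons that start with A (11 of 49) and the branched-chain (14 of 47), amide (6 of 22) and sulphur (11 of 35) classes. After centring the lower genes in these lists numbered 2 for tyrosine and 2 for anticodons that start with A, with no lower call in the others. Lysine, with 0 of 19 genes past the test in either direction, and the basic class, with 1 higher and 1 lower of 46, were called higher than other tRNAs; after centring 14 lysine and 24 basic genes were higher and 0 lower.

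The 2 hairpins against 1 target test whether a change follows the target. For MEF2C, the log2 ratios to NTC of hairpin 1 and hairpin 2 correlated across 292 genes with a Pearson r of 0.88 and a Spearman rho of 0.85, where unchanged hairpins that share the NTC libraries gave between 0.35 and 0.62 in simulations. Genes are not independent replicates. With each hairpin tested alone, 98 genes, among them tRNA-Asn-GTT-3-1 and tRNA-Val-CAC-2-1, were lower with both, where the product of the counts gives 53.4, and 18 were higher with both, where it gives 4.2, without allowance for the NTC libraries that the hairpins share. In the opposite direction lay 3 genes. The hairpins also differed from each other at 145 genes, 125 of them lower with hairpin 2, with the spread estimated over all 15 libraries. A fit of the libraries of these hairpins alone called 40. The median gene changed by -0.17 with hairpin 1 and -0.67 with hairpin 2.

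For ZNF460, the log2 ratios of the 2 hairpins correlated across genes with a Pearson r of 0.10 and a Spearman rho of 0.13. Unchanged hairpins gave a Pearson r of 0.36 to 0.60 in simulations, but changes with 1 hairpin alone lower r, so these values cannot be ranked. The covariance was 0.0193, below the 0.0236 to 0.0496 simulated. Among genes with a mean of at least 100 TPM it was 0.0107, within the 0.0099 to 0.0232 simulated. Hairpin 1 alone called 98 genes and hairpin 2 alone 43. Both called 15 genes in the same direction, 3 higher and 12 lower, among them tRNA-Ala-AGC-7-1, tRNA-Leu-TAG-2-1, tRNA-Tyr-GTA-5-1 and tRNA-Glu-CTC-1-2, where the products of the counts give 0.65 and 8.93. The products take the hairpins as independent, while both are set against the same NTC libraries, so these counts are no evidence of a shared response. In opposite directions lay 9 genes, among them tRNA-SeC-TCA-1-1, which decodes UGA as selenocysteine, at 280.1 ± 13.1 TPM in NTC, 180.4 ± 12.4 with hairpin 1 and 500.8 ± 16.3 with hairpin 2. The hairpins differed from each other at 84 genes, 66 higher and 18 lower with hairpin 2, and at 162 in a fit of their libraries alone. Replicates of 1 MEF2C hairpin correlated at 0.978 to 0.989 and those of 1 ZNF460 hairpin at 0.995 to 0.997. With this unequal spread, the 84 genes here and the 145 of the MEF2C hairpins do not rank the targets. The arginine pool was 5792 ± 469 TPM with hairpin 1 and 13020 ± 574 with hairpin 2, against 8820 ± 1447 in NTC. The aspartate pool lay the other way, at 552 ± 39.5 TPM with hairpin 1 and 176 ± 13.5 with hairpin 2, against 237 ± 38.8 in NTC.

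**Figure D3:**
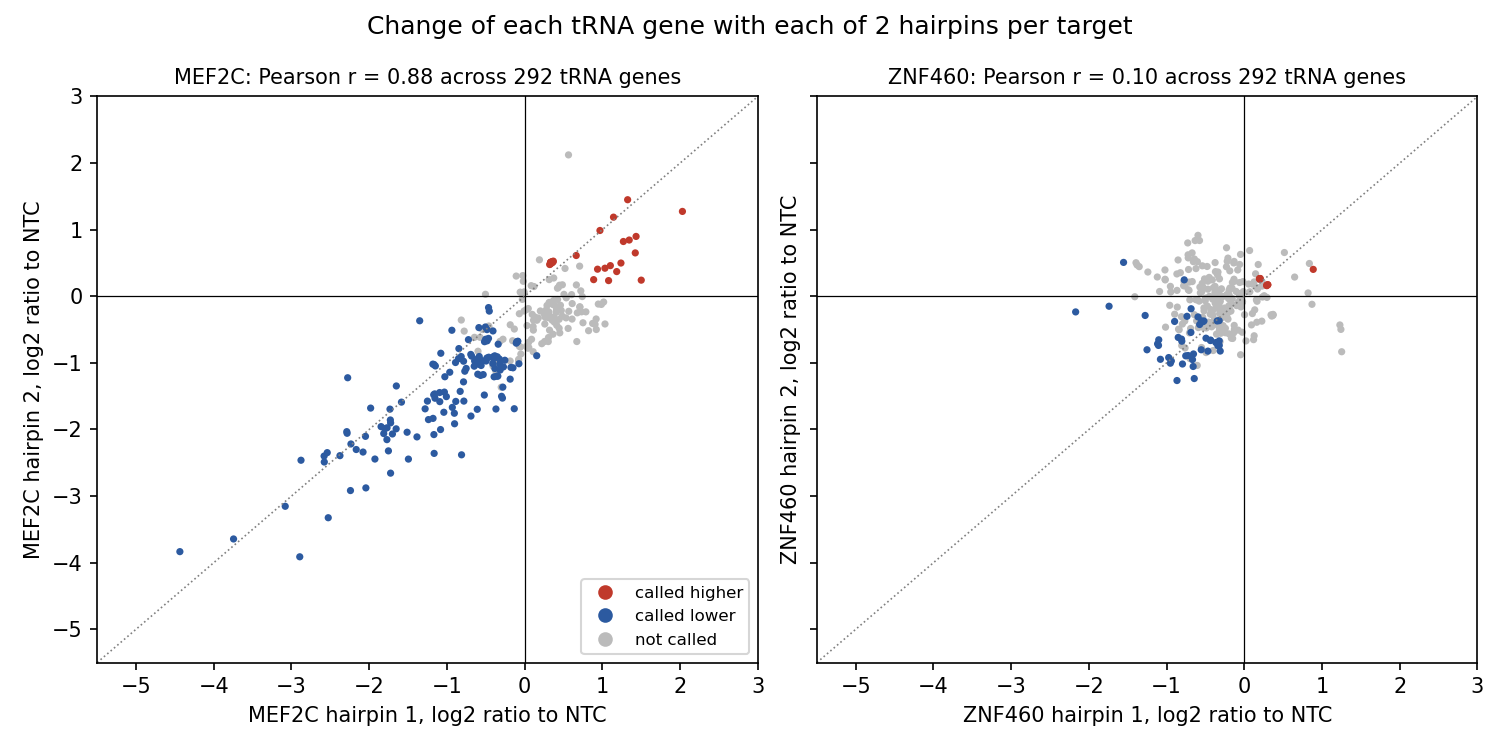
Log2 ratio to NTC of each of 292 tRNA genes with hairpin 2 (vertical) against hairpin 1 (horizontal), for MEF2C and ZNF460, coloured by the call on the mean of both hairpins with values as deposited; the dotted line marks equal values. The genes lie along a diagonal for MEF2C (r = 0.88) and in a cloud for ZNF460 (r = 0.10), and the split into higher and lower changes with the scaling of the libraries.

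The third comparison set the libraries of the 2 targets against each other, with the NTC libraries entering only the estimate of the variance. In ZNF460 libraries tRNA-Asn-GTT-3-1 was 15.3-fold higher than in MEF2C libraries (log2 3.94, SE 0.219, adjusted p = 1.05e-11 in limma, n = 6 each), tRNA-Lys-CTT-8-1 8.27-fold, tRNA-Lys-CTT-5-1 7.52-fold, tRNA-Arg-CCG-2-1 5.30-fold and tRNA-Arg-ACG-2-2 4.67-fold higher. Lower were tRNA-Thr-TGT-1-1 by 3.70-fold, tRNA-Ser-TGA-4-1 by 2.81-fold, tRNA-Ala-AGC-5-1 by 2.40-fold, tRNA-Ala-AGC-7-1 by 2.37-fold and tRNA-Ala-TGC-1-1 by 2.18-fold. The libraries of the 2 targets did not overlap for any of these 10 genes. Of the 10, tRNA-Ala-AGC-5-1 alone lost its call under an alternative, with the hairpins as the units of replication.

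Between the targets 214 of 292 genes differed in limma, 136 higher and 78 lower with ZNF460 knockdown, and the median gene differed by 0.34. After centring 229 passed, 126 higher and 103 lower, and after scaling to the tRNAs other than glycine 198 passed, 62 higher and 136 lower. Hairpin number as a replicate block, though the numbers name different sequences, gave 187, and the hairpins as the units of replication gave 72. Of 21 isotype pools 17 passed, 11 higher and 6 lower, with asparagine 6.17-fold, arginine 3.31-fold, tryptophan 3.16-fold and glutamine 2.32-fold higher and initiator methionine 2.26-fold lower. After centring 18 passed, 10 higher and 8 lower. After scaling to the tRNAs other than glycine 17 passed, 5 higher and 12 lower, and glutamate, phenylalanine, selenocysteine and valine lost their calls. Glycine was 1.15-fold lower as a sum but higher by 0.21 as a mean of log2 values. Leucine and serine were higher as deposited (0.32 and 0.38) but lower after scaling to the tRNAs other than glycine (-0.33 and -0.27). Proline lost its call without MEF2C hairpin 1 replicate 2 or 3, MEF2C hairpin 2 replicate 1 or 2, ZNF460 hairpin 1 replicate 2 or 3, or any replicate of ZNF460 hairpin 2, and tyrosine without MEF2C hairpin 2 replicate 2. Among the lists, 27 of 27 arginine, 19 of 19 glutamine, 22 of 22 amide and 41 of 46 basic genes were higher with ZNF460 knockdown, the same numbers as adjusted over each list alone. After scaling to the tRNAs other than glycine 16, 15, 16 and 23 of these were higher. Of 35 sulphur genes 22 were lower, also adjusted over the list alone. The preset-correlation test called 15 lists, none of which passed with an estimated correlation (adjusted p = 0.673 with an estimated correlation for arginine, the lowest, and adjusted p = 0.720 with an estimated correlation for alanine, the highest). It called arginine, glutamine, glutamate, lysine, the amide, basic and acidic classes and anticodons that start with C higher than other tRNAs. It called alanine, cysteine, glycine, tyrosine, the small and sulphur classes and anticodons that start with G lower than other tRNAs.

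The overlap of the 2 responses asked which tRNA genes changed with both targets. Lower in both were 19 genes, among them tRNA-Leu-TAG-1-1 and tRNA-Leu-TAG-2-1, where the product of the counts gives 21.6; 0 were higher in both, where it gives 0.83, and the product leaves out that the targets share the NTC libraries. Of the 19, tRNA-Val-CAC-2-1 and tRNA-Arg-ACG-2-3 lay below every NTC library in the 3 libraries of ZNF460 hairpin 1 and above every NTC library in the 3 of hairpin 2, so they were lower with ZNF460 only on average. The 8 Glu-CTC genes were lower with MEF2C and higher with ZNF460 knockdown as deposited. The MEF2C part did not pass for the Glu-CTC pool after centring (log2 0.066, adjusted p = 0.733 in limma). Across genes the changes with the 2 targets correlated with a Pearson r of 0.09, against 0.57 to 0.75 simulated for unchanged groups that share NTC. Changes with 1 target alone lower r, so these values cannot be ranked. The covariance of the changes was 0.0282, within the 0.0265 to 0.0483 simulated.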

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

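The tests of rescaling without glycine, of a shared batch, of noise between libraries, of an unequal loss, of the hairpin's sequence and of splits that keep constructs whole were chosen only after the result was seen.

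MEF2C libraries differed from NTC at 164 of 292 tRNA genes. Lower depth of the MEF2C libraries is argued against, because thinning every library to 498793 reads left at least 149 calls in 20 draws, and a larger share of glycine tRNA as the whole cause is argued against by 166 calls after rescaling to the other tRNAs. A library or purification batch shared by the MEF2C libraries stays open: the lowest correlation between libraries of the 2 MEF2C hairpins was 0.972, above the highest between an NTC and a MEF2C library, 0.960, which a shared batch and a shared target would both give, so they cannot be told apart without a record of batches. A response to loss of MEF2C also stays open as a hypothesis and may account for the 98 genes lower with both hairpins.

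Most of the genes that differed with MEF2C knockdown were lower, 83.5%. After rescaling to the tRNAs other than glycine 42.2% were lower, and the predominance of lower genes may come from the larger glycine share or from a common fall of the other tRNAs, which this rescaling cannot tell apart. An earlier criterion, how many of the 143 calls outside glycine kept their direction after rescaling, gave 84 with 4 in the opposite direction; it decided neither way and was replaced after it was seen. Whether glycine tRNA rose or the others fell cannot be read from values that share a fixed total, and no biological explanation was tested.

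The 2 ZNF460 hairpins differed from each other at 84 genes, and at 162 in a fit of their libraries alone. The arginine pool was higher with hairpin 2 than with hairpin 1 by 1.17 and the selenocysteine pool by 1.47 on the log2 scale. The aspartate pool was lower (log2 -1.64). Unequal depth is argued against, because at least 73 genes differed after thinning. Noise that hides a shared response, and an unequal loss of ZNF460 that changes only its size, are each argued against as the whole cause. With replicate variance and the shared NTC taken out, the Pearson r of the 2 hairpins' changes was -0.0718 (95% interval over isodecoders -0.302 to 0.144). For MEF2C it was 0.956. The bound for this judgement was set after the value was seen. Effects of 1 hairpin alone also lower this r, so a shared response beneath them is not excluded. This test replaced the 28.8% of genes past the test of the difference, a restatement of the pattern. Effects of 1 hairpin's sequence and a batch that follows the hairpin cannot be told apart: the Pearson r of 0.10 across genes (0.0989) would follow from either, and the labels mark no batch. A response to ZNF460 itself was not separated from these: both hairpins called 15 genes in the same direction, a number that the shared NTC libraries can raise, and 9 in opposite ones.

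The MEF2C hairpins differed from each other at 145 genes, and at 40 in a fit of their libraries alone. In the 6 MEF2C libraries tRNA-Arg-ACG-2-1 was low in hairpin 1 replicate 1, at 22.97 TPM against 33.3 for the nearest library. In hairpin 1 replicate 3 tRNA-Trp-CCA-4-1 was high, at 291 TPM against 195 for the nearest. The tryptophan pool was high in the same library, at 450 TPM (449.8) against 321. Of 150 groups tested for an outlying library 3 stood out, where chance gives 7.5.

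Other splits of the libraries were fitted as 2 groups; they exchange single libraries, although 3 libraries share each construct, so they do not speak of chance between hairpins. For MEF2C knockdown against NTC, 1 of 84 splits, the real one, gave as many calls. It gave 123 against 57 in the highest other, the 3 libraries of hairpin 2 against the rest. That speaks against chance among single libraries only, since any difference between constructs would give it too. For ZNF460 knockdown against NTC 2 of 84 splits gave as many; the real one gave 60, and the highest other, the 3 libraries of hairpin 1 against the rest, gave 108, which points to a structure of the samples by hairpin, so chance is not excluded for the knockdown. Between the targets 1 of 100 splits, the real one, gave as many calls, with 175 against 80, which again speaks of single libraries only. For isotype pools of MEF2C, 1 of 84 splits gave as many calls, with 13 against 9, the latter again the libraries of hairpin 2. Between the targets it was 1 of 100, with 11 against 6. Neither excludes chance between constructs. For ZNF460 pools 2 of 84 gave as many, with 6 against 11, again the libraries of hairpin 1. Only 3 splits keep each construct whole, too few for a test; they gave 123, 57 and 1 genes for MEF2C, 60, 108 and 36 for ZNF460 and 175, 0 and 0 between the targets, the real split first. For 3 libraries against 3 the 10 splits are too few; the real split gave 136 and 150 calls for MEF2C hairpins 1 and 2 against NTC, 149 and 125 for ZNF460 hairpins 1 and 2, 40 between the MEF2C hairpins and 162 between the ZNF460 hairpins, and the highest other in each gave 0.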

How the results depend on the processing

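Tests with the hairpin as the unit, the replicate number as a block, the tRNAs other than glycine as the scale, and thinned reads were chosen only after the result was seen. The 2 purifications named in the labels could not be set apart, so a fit within each was not run. The 15 fits that left out 1 library gave 145 to 183 genes for MEF2C against NTC, 0 to 70 for ZNF460 against NTC and 200 to 223 between the targets, and 136 of 164, 0 of 55 and 190 of 214 calls were kept in all of them. Isotype pools ranged over 14 to 16, 0 to 8 and 16 to 18. With a mean of at least 100 TPM 104 of 153 genes passed for MEF2C and 129 of 153 between the targets, because fewer genes were tested. With isodecoders summed 34 of 193 passed for ZNF460 and 138 of 193 between the targets, because copies no longer count separately. With the hairpin as the unit, which leaves fewer values, the counts were 43, 0 (1 with an unadjusted p under 0.05 in limma) and 72. For ZNF460 limma called 26 genes without a trend, 123 on the NTC and ZNF460 libraries alone and 98 with hairpin 1 alone, and 11 isotype pools with the tRNAs other than glycine as the scale; the cause was not tested. With an estimated correlation 0 lists passed for MEF2C, 3 for ZNF460 and 0 between the targets. Replicate numbers do not pair the libraries: residuals of same-numbered libraries correlated at a median of 0.017, and the number as a block gave 163, 60 and 212 genes. Hairpin number as a replicate block gave 187 genes between the targets. Reads thinned to 498793 gave 149 to 157, 25 to 50 and 198 to 206 genes.

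The genes tRNA-Gly-GCC-1-1 to tRNA-Gly-GCC-1-5 passed in neither knockdown against NTC as deposited. They changed direction for MEF2C with hairpin 1 alone (-0.0070, -0.011, -0.025, -0.042 and -0.012) and, for tRNA-Gly-GCC-1-3 and tRNA-Gly-GCC-1-4, with voom (-0.00016 and -0.0066). For ZNF460 they turned after centring (0.41, 0.41, 0.41, 0.41 and 0.41) and with hairpin 2 alone (0.037, 0.028, 0.032, 0.028 and 0.037). For ZNF460 tRNA-SeC-TCA-1-1 turned with hairpin 1 alone (-0.63) and without glycine in the scale (-0.012), and tRNA-Thr-CGT-4-1 without NTC replicate 3 (-0.042; the fits without 1 library ranged from -0.042 to 0.387). The glycine pool turned as a mean of log2 values, to -0.21 for MEF2C and 0.21 between the targets. After centring the MEF2C values of glutamate, isoleucine, methionine and serine were 0.14, 0.067, 0.21 and 0.14, and without glycine in the scale 0.10, 0.031, 0.17 and 0.10. Of the latter, glutamate passed as higher (adjusted p = 0.0459 in limma). The ZNF460 values of glutamine and valine after centring were 0.022 and 0.16. Between the targets leucine and serine were -0.33 and -0.27 without glycine in the scale. Both scalings move the genes of a library by nearly the same amount, which by construction turns values nearer to 0 than the shift; the cause of the other turns was not tested.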

Other observations

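Ratios between isoacceptors of 1 amino acid within a library do not depend on how libraries are scaled; these ratios were chosen as tests only after the result was seen. All pairs of isoacceptors of an amino acid were taken, so 1 changed isoacceptor can enter several ratios. Counts of ratios here are therefore not counts of independent results. With MEF2C knockdown 36 of 46 ratios differed from NTC in limma, in 12 of 13 isotypes, and 27 ratios passed in the same direction with each hairpin. The ratio of valine anticodons CAC to TAC fell 3.77-fold (log2 -1.91, SE 0.112), from 1.89 in NTC to 0.425 and 0.593 with the hairpins. The ratio of leucine anticodons AAG to CAG fell 3.40-fold (log2 -1.77, SE 0.143), and that of lysine CTT to TTT fell 2.65-fold, from 43.2 to 14.1 and 18.8. The ratio of initiator to elongator methionine tRNA rose 2.14-fold (log2 1.10, SE 0.142), and that of glycine GCC to TCC rose 2.08-fold, from 195.6 to 385.9 and 427.6. For the MEF2C ratios 1 of 84 splits, the real one, gave as many calls, 32 against 2 in the highest other. This speaks against chance among single libraries and does not cover chance between constructs.

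With ZNF460 knockdown 10 of 46 ratios differed from NTC, in 3 isotypes, and 1 passed in the same direction with each hairpin, leucine TAA to TAG, which rose 1.40-fold (log2 0.48, SE 0.133; 0.41 and 0.56 with hairpins 1 and 2). The ratio of arginine anticodons ACG to TCT fell 3.02-fold with hairpin 1 (log2 -1.60) and was at a log2 of 0.0058 with hairpin 2 (adjusted p = 0.970 in limma). The ratios of leucine AAG to CAA (log2 -1.17 and -0.47) and CAA to TAG (1.10 and 0.43) passed with hairpin 1 and did not with hairpin 2 (adjusted p = 0.139 for each). In the splits of these libraries 4 of 84 gave as many calls; the real one gave 2 and the highest other, hairpin 1 against the rest, 25, which points to a structure of the samples by hairpin.

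The share of the TPM total outside the listed genes was between 3.03% and 3.46% in NTC libraries and between 1.72% and 2.86% in MEF2C libraries. It was between 3.55% and 3.68% with ZNF460 hairpin 1 and between 1.47% and 1.57% with hairpin 2. Across 292 genes the change with MEF2C knockdown had a Spearman rho of -0.05 with mean abundance and the change with ZNF460 knockdown 0.32; genes are not independent replicates.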
